A study of Mus musculus with 14 samples.

How the data were processed

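Strand-specific mRNA sequencing libraries (per the labels' protocols) of the mouse lung adenocarcinoma line TR.1 were analysed from 2 deposited tables of genes by libraries, 1 for acute treatment and 1 for resistant cultures. Per the submitters' processing notes, reads were checked with FastQC, aligned to mm10 with STAR and analysed with edgeR, with no versions given. The deposited tables are called CPM in their names, but each column holds whole numbers that sum to between 60.7 and 89.8 M, so the deposited values were taken as raw counts per gene. The annotation, the counting tool and the strand setting are not given in the sources used here. Each table has 55415 rows, of which 55391 symbols matched GENCODE M21 (mm10) without regard to case and 24 are 5-digit numbers. These 24 rows hold between 0.163 and 0.215% of the counts of a library, and they stayed in library sizes and tests but are not named. The symbols of 8921 matched rows were re-cased, and 114 symbols lie at more than 1 position. All deposited columns were used.

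The plan written before the data were examined assumed CPM values and limma on log2(CPM + 1). Since the values are counts, edgeR's quasi-likelihood test with TMM scaling replaced it, and limma became an alternative. Analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. Genes were kept with a CPM of at least 1 in at least 4 libraries of the acute table, which left 13209, or in at least 2 libraries of the resistance table, which left 14389. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F and are approximate. CPM values in the text are TMM-scaled, with the mean ± SD over libraries.

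The acute comparison had day as a block and treatment as the effect, and its interaction with day as a number gave the slope per day. The labels mark each day as a batch shared by the arms, and the deviations of same-day libraries from their arm means correlated at 0.516 to 0.675 over 10666 genes. Libraries of different days correlated at up to 0.620, so these values also reflect the time course and do not by themselves show a shared batch. The resistance comparisons came from 1 fit of 3 groups to 6 libraries, which share 1 estimate of the spread. The tables were not merged. Gene lists, 29 in number and written before the data were examined, were tested with limma camera on log2(CPM + 1), at a preset correlation between genes of 0.01 and, as an alternative, with the correlation estimated from the data. Lists needed at least 4 measured genes, and calls within a list were also adjusted over the list alone. The genes that changed acutely, up to 200 per direction, were tested as sets in the resistance comparisons.

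Genes named in the text are the 10 with the largest rise and the 10 with the largest fall among those called, or 5 and 5 for the slope by day and for the comparison of the resistant groups. They needed a mean CPM of at least 5, the same direction in each day pair or no overlap between groups, and a name other than a Gm or Rik identifier. Ret, Trim24, Met and up to 4 members of each list with the lowest p were added by the same rule. Epcam, Col1a1, Mki67, Cdh1, Irf7, Dcn and Oasl2 in the resistant groups were chosen after their values were seen.

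Each fit was tested on simulated data with 200 changed genes. In the acute design it recovered 58.2, 89.6 and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 14 unchanged genes called. Recovery was 59.7, 92.5 and 98.5% for selpercatinib-resistant, 52.2, 79.1 and 100% for pralsetinib-resistant cells and 59.7, 86.6 and 100% between them, with 17, 14 and 11 unchanged genes called. For the slope by day 13% of genes changed 1.2-fold per day and 87% of those changed 1.5-fold were recovered. The real acute fit called 53.5% of its genes, and the fits against parental cells 69.6 and 70.3%. These are far larger shares than the simulations changed, so the simulated rates need not hold for those fits. Alternatives covered the pseudocount, the filter, scaling, DESeq2, limma variants, the day term, the block, the number of genes in the acute sets, the fry test and the omission of each library or day. Dose was not fitted, since only the pralsetinib-resistant libraries differ in dose within a group and each dose has 1 library.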

Results

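Transcript levels were measured by RNA sequencing in TR.1, a mouse lung adenocarcinoma cell line with a Trim24-Ret fusion, an oncogene in which the Ret receptor tyrosine kinase is joined to Trim24. Selpercatinib and pralsetinib are selective inhibitors of the RET kinase, and DMSO is the solvent given to the controls. The acute table held 8 libraries, with 1 DMSO and 1 selpercatinib library (100 nM) at each of days 1, 2, 3 and 5. The resistance table held 6 libraries, with 2 of parental DMSO cells, 2 of selpercatinib-resistant cells (500 nM) and 2 of pralsetinib-resistant cells, at labelled doses of 200 and 400 nM. The labels' protocol has the resistant cultures growing in 400 to 500 nM, which does not match the 200 nM label, so that dose is uncertain. By the same protocol the resistant cultures started at 30 nM, and they and the parental DMSO cells were cultured for about 60 days. Totals ran from 68.6 to 89.8 M counts per library in the acute table and from 60.7 to 81.9 M in the resistance table. At this depth 3 counts corresponded to between 0.0334 and 0.0526 CPM, and intervals and floors given here cover counting error only. Libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 7.02 for the parental pair, 13.0 for the selpercatinib-resistant pair and 44.8 for the pralsetinib-resistant pair. The labels do not say that the libraries of a group came from separately derived cultures, so p-values measure only the spread between these libraries. That spread may be technical, except that the pralsetinib-resistant pair also differs in labelled dose and the acute libraries in day.

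The acute comparison asks what RET inhibition changes within 5 days. ERK pathway target genes fell at every day. Etv5 and Etv4, ETS transcription factors induced by ERK signaling, fell by 3.33 (SE 0.08) and 2.80 (SE 0.08) on the log2 scale over 4 day pairs, and the feedback inhibitors Spry4 and Dusp6 fell by 3.74 (SE 0.16) and 2.39 (SE 0.07). Dusp6, a phosphatase that acts on ERK, averaged 359 ± 52.0 CPM in DMSO and 68.5 ± 9.17 CPM in selpercatinib (SD, n = 4 each). Among 19 measured ERK output genes, 16 fell and 3 rose, with the same counts when adjusted over the list alone and a median log2 change of -2.00. DNA replication genes fell in 21 of 26 cases and rose in 1, among them Tk1, a thymidine kinase, at -1.38 (SE 0.12) and Uhrf1, a maintenance methylation factor, at -1.24 (SE 0.12). Mitosis genes fell in 23 of 26 cases, or 24 when adjusted over the list alone, among them Top2a at -1.16 (SE 0.10) and Bub1 at -0.99 (SE 0.10), a topoisomerase and a spindle checkpoint kinase. Genes of nucleolar ribosome biogenesis fell in 19 of 22 cases, with Ncl, which encodes nucleolin, at -1.01 (SE 0.10) and Fbl, which encodes fibrillarin, at -0.95 (SE 0.08). The 4 cell cycle genes named here had a fall of similar size in a fit without the day, from -1.04 to -1.41, and lost the call there. Limma camera with Benjamini-Hochberg adjustment called these lists at an adjusted p = 5.32e-06 for ERK output, 6.03e-06 for replication and 4.79e-06 for both mitosis and ribosome biogenesis. With an estimated correlation the calls were lost, at adjusted p = 0.590 for ERK output and 0.730 for the other lists.

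**Figure D1:**
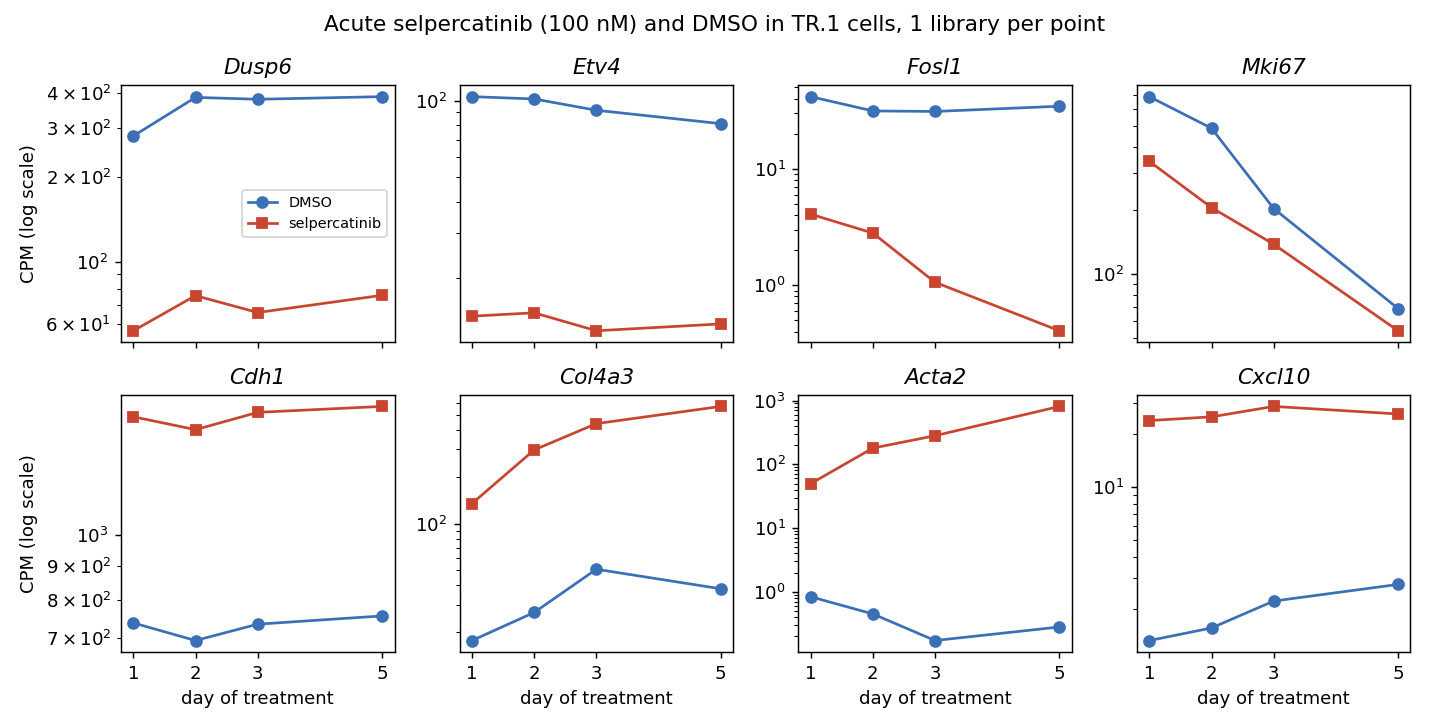
CPM on a log axis against day of treatment for 8 genes, with 1 library per point, circles for DMSO and squares for selpercatinib. Dusp6 in the selpercatinib libraries stayed between 56.6 and 75.8 CPM, against 281 to 388 CPM in DMSO, while Mki67 fell in both arms and was 69.0 CPM in DMSO on day 5.

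Of 23 glycolysis and hypoxia genes 16 fell and 1 rose, or 19 and 1 when adjusted over the list alone, including Pdk1, a kinase that restrains pyruvate dehydrogenase, at -1.66 (SE 0.21), and the glucose transporter gene Slc2a1 at -1.03 (SE 0.14). In the list of ATF4 and unfolded protein response genes 10 of 22 were lower than in DMSO and the other 12 did not pass the test. The mean difference of that list between arms was -0.0647 on day 1 and -0.728 on day 5 (log2). From day 1 to day 5 its level rose by 1.08 in DMSO and by 0.42 in selpercatinib, so the difference reflects a smaller rise. The members of that list with the lowest p were Phgdh, Shmt2 and Psat1, enzymes of serine and glycine synthesis, at -1.13 (SE 0.07), -0.94 (SE 0.09) and -0.84 (SE 0.09). Camera's adjusted p was 0.000102 for glycolysis and 0.0163 for the ATF4 list, and 0.730 for both with an estimated correlation.

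Epithelial adhesion, antigen presentation, interferon-stimulated and lysosomal genes rose. Cdh1, which encodes E-cadherin, averaged 731 ± 26.0 CPM in DMSO and 1509 ± 51.1 CPM in selpercatinib (SD, n = 4 each), a log2 change of 1.05 (SE 0.08), and the desmosome gene Dsp rose by 1.51 (SE 0.07). The membrane protease gene St14 rose by 1.45 (SE 0.10), and in all 17 of 22 epithelial genes rose and none fell. Of 13 antigen presentation genes 12 rose, among them Tapbp, which loads peptides on MHC class I, by 2.18 (SE 0.09), and B2m, its light chain, by 1.16 (SE 0.09). Interferon-stimulated genes rose in 14 of 17 cases, with Ddx58, which encodes the RNA sensor RIG-I, at 1.90 (SE 0.14) and Ifit2 at 2.03 (SE 0.23). Lysosome and autophagy genes rose in 16 of 23 cases and fell in 1, with the protease gene Ctsd at 1.39 (SE 0.09) and Grn at 0.95 (SE 0.07). These counts were the same when adjusted over the list alone. Camera's adjusted p was 5.40e-06 for the epithelial list, 1.34e-05 for antigen presentation, 3.31e-05 for interferon and 1.47e-05 for lysosome. Each of these lists had an adjusted p of 0.590 with an estimated correlation.

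Alveolar type 1 genes rose in 11 of 16 cases and fell in 3, and YAP/TEAD target genes rose in 13 of 21 cases and fell in 6, or 7 when adjusted over the list alone. The basement membrane collagens Col4a3 and Col4a4 rose by 3.36 (SE 0.17) and 2.86 (SE 0.12), Akap5 by 4.17 (SE 0.20) and Pdpn by 3.25 (SE 0.21). Amotl2 and Gadd45b, members of the YAP/TEAD list, rose by 1.82 (SE 0.10) and 1.84 (SE 0.09). Mitochondrially encoded transcripts, included as a sign of RNA quality, rose in 7 of 13 cases, with mt-Nd6 at 0.49 (SE 0.09) and mt-Nd4 at 0.47 (SE 0.10), and took from 1.56 to 2.12% of counts in DMSO and from 1.97 to 2.33% in selpercatinib. The camera adjusted p was 0.0248, 0.0170 and 0.0393 for these lists in the order named. With an estimated correlation it was an adjusted p of 0.590 for the alveolar and YAP/TEAD lists and 0.730 for the mitochondrial list.

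The 10 largest rises, by the rule fixed before the data were examined, included 3 contractile genes. Acta2, which encodes smooth muscle actin, went from 0.436 ± 0.292 CPM in DMSO to 329 ± 333 CPM in selpercatinib (SD, n = 4 each). Folds in this paragraph come from the edgeR fit with the day as a block and are not ratios of these means. In that fit Acta2 rose 501-fold, and Myl9 and Cnn1, a myosin light chain and calponin, rose 283-fold and 204-fold. Cytip rose 254-fold, Pdzk1ip1 153-fold, the aggrecan-cleaving protease gene Adamts5 71.5-fold, the neuropeptide precursor Nts 62.5-fold, Sema3d 52.4-fold, the growth factor gene Tgfb2 50.6-fold and Pappa 45.5-fold. The largest falls were in Aqp8, a water channel gene, at 109 ± 43.0 CPM in DMSO and 0.197 ± 0.336 CPM in selpercatinib, and in Nptx1, Mrc1, Slc14a1, Fam78b, Ptpru, Stc1 and Has2, which were between 29.9-fold and 89.1-fold lower. Prl2c3 and Prl2c2 were 50.9-fold and 44.8-fold lower, but they are near-identical placental prolactin copies among which reads can be split, so their values are uncertain. edgeR's quasi-likelihood test with the day as a block found 7072 of 13209 genes changed, 3513 higher and 3559 lower, of which 1103 and 790 changed at least 2-fold.

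Ret lies on chromosome 6 from 118151745 to 118197718 (mm10), Trim24 on the same chromosome from 37870811 to 37966296, and Met, a receptor tyrosine kinase gene, from 17463800 to 17573980. Gene counts do not separate fusion transcripts from those of the intact genes. Ret fell by 0.62 (SE 0.09) and Trim24 by 0.65 (SE 0.09) on the log2 scale after acute selpercatinib, with edgeR adjusted p = 0.00165 and 0.00130 by Benjamini-Hochberg. Met did not pass the test, at 0.04 (SE 0.07) and adjusted p = 0.646 in the same edgeR fit.

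The second acute comparison asks whether the difference between arms grew or shrank from day 1 to day 5. It grew for Acta2 and Myl9. The edgeR slope of the log2 ratio per day was 1.40 (SE 0.24) for Acta2 and 1.06 (SE 0.15) for Myl9. On the log2(CPM + 1) scale, where a trend is flatter for levels near 0, the arms differed in Acta2 by 4.79 on day 1, 6.96 on day 2, 7.91 on day 3 and 9.30 on day 5. The calcium channel gene Cacna1g, the phosphatase gene Ptprz1 and the protease gene Tll1 had slopes of 0.94 (SE 0.11), 0.93 (SE 0.12) and 0.73 (SE 0.10). The slope was negative for Mrc1 at -1.30 (SE 0.09), the protease inhibitor gene Serpinb2 at -1.28 (SE 0.13), Ifi209 at -1.04 (SE 0.16), Fam78b at -0.99 (SE 0.13) and Cpa4 at -0.92 (SE 0.17). In limma on log2(CPM + 1) these 5 negative slopes lay between -0.65 and -0.17 and none passed the test. Ret, Trim24 and Met did not pass the test, with slopes of -0.10 (SE 0.04), -0.09 (SE 0.05) and -0.02 (SE 0.05). Among ERK output genes 2 of 19 had a negative slope, or 5 when adjusted over the list alone, and these 2 were Fosl1 at -0.82 (SE 0.11) and Dusp5 at -0.31 (SE 0.05). Fosl1 fell short in limma on log2(CPM + 1), at -0.43 and an adjusted p of 0.0684. Interferon-stimulated genes had 3 negative slopes among 17, or 9 when adjusted over the list alone, where 1 was positive. On the log2(CPM + 1) scale Xaf1 had a log2 ratio of 2.12 on day 1 and 0.57 on day 5, and Oasl2 of 1.78 and -0.70. The mean level of the interferon list rose in both arms from day 1 to day 5, by 1.29 in DMSO and 0.636 in selpercatinib. Glycolysis and hypoxia genes had 3 negative slopes among 23, or 11 and 1 positive over the list alone, with the oxygen sensor gene Egln3 at -0.66 (SE 0.09) and Ankrd37 at -0.72 (SE 0.11), or -0.34 in limma on log2(CPM + 1). The mean level of this list rose by 0.499 in DMSO from day 1 to day 5 and fell by 0.306 in selpercatinib, so the widening also reflects a rise in the controls. In the mitosis list 1 of 26 genes passed, Plk1 at 0.32 (SE 0.06), and the list shifted upward with a median slope of 0.14, while its level in DMSO itself dropped by 2.58 on the log2 scale from day 1 to day 5.

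Camera called 9 lists in this comparison. The adjusted p was 2.55e-08 for mitosis and 0.0492 for replication, both with positive median slopes, against adjusted p = 0.606 and 0.842 with an estimated correlation. The lists with negative medians also held ATF4 genes, where 1 of 22 passed, gut and gastric lineage genes, where none of 14 passed, receptor tyrosine kinases other than Ret, where 2 of 22 passed, and drug efflux transporters, where 1 of 9 passed. For these lists camera's adjusted p was 1.66e-05 for glycolysis and hypoxia, 0.000239 for interferon, 2.69e-05 for ATF4, 0.0125 for gut and gastric lineage, 0.0299 for receptors, and 0.0485 for both ERK output and efflux transporters. These had an adjusted p with an estimated correlation of 0.345, 0.345, 0.468, 0.594, 0.638, 0.606 and 0.594 in the same order. edgeR's quasi-likelihood interaction test called 164 of 13209 genes, 60 with a positive and 104 with a negative slope, and 2189 had an unadjusted p under 0.05. Without day 1 or without day 2 edgeR called 0 genes, with 775 and 1202 at an unadjusted p under 0.05, while leaving out day 3 or day 5 gave 1053 and 475. The count thus depends on which days enter the fit, and the effect of fewer libraries was not tested apart from it.

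The resistance comparisons ask how cultures that grow in a RET inhibitor differ from parental cells. In selpercatinib-resistant cells most measured genes of the epithelial list fell, and most of the fibroblast, interferon and chemokine lists rose. Epcam, an epithelial adhesion gene, averaged 242 ± 4.37 CPM in parental cells and 0.621 ± 0.140 CPM in selpercatinib-resistant cells (SD, n = 2 each), 392-fold lower. The tight junction genes Cldn7 and Cldn4 fell by 7.26 (SE 0.11) and 7.33 (SE 0.16) on the log2 scale and St14 by 8.70 (SE 0.14), whereas Cdh1 fell by 1.83 (SE 0.38). Of 20 measured epithelial genes 19 fell and 1 rose. Col1a1, a fibrillar collagen gene, rose from 7.79 ± 0.612 to 1333 ± 115 CPM, and the fibroblast marker list, in which 10 of 10 measured genes rose, included Col3a1 at 10.29 (SE 0.48), Fbn1 at 5.00 (SE 0.21) and Col5a1 at 3.21 (SE 0.12). The list holds 15 genes, of which the filter kept 10. Dcn and Col3a1, at 0.0287 and 0.0661 CPM in parental cells, passed the filter only through resistant libraries. For such genes a fall could hardly be called, so the count is partly set by the filter. Mesenchymal genes rose in 10 of 20 cases and fell in 3, with Lox, a collagen cross-linking enzyme, at 9.25 (SE 0.36), Sparc at 2.49 (SE 0.09), Mmp2 at 4.56 (SE 0.28) and Acta2 at 11.59 (SE 0.66). Camera's adjusted p was 1.51e-08 for the epithelial, 9.10e-05 for the fibroblast and 0.0457 for the mesenchymal list. Their adjusted p with an estimated correlation was 0.434, 0.298 and 0.631.

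Interferon-stimulated genes rose in 25 of 26 cases and fell in 1, with Ifit1 at 6.91 (SE 0.24), Xaf1 at 4.27 (SE 0.12), Ifit2 at 3.82 (SE 0.13), Oasl2 at 3.48 (SE 0.13) and the transcription factor gene Irf7 at 3.17 (SE 0.28). Antigen presentation genes rose in 13 of 19 cases and fell in 4, with the invariant chain gene Cd74 at 4.36 (SE 0.22), the immunoproteasome gene Psmb8 at 5.59 (SE 0.35), the peptide transporter gene Tap1 at 4.22 (SE 0.29) and Tapbp at 1.81 (SE 0.06). Chemokine and cytokine genes rose in 16 of 26 cases, or 17 when adjusted over the list alone, and fell in 8. Cxcl12 went from 0.911 ± 0.0508 to 772 ± 107 CPM and Tgfb2 from 2.19 ± 0.0718 to 175 ± 13.6 CPM, and the neutrophil chemokine genes Cxcl5 and Cxcl1 rose by 4.61 (SE 0.08) and 2.72 (SE 0.06). Cxcl12, below the minimum CPM of 1 in parental cells, likewise passed the filter only through resistant libraries. Camera's adjusted p was 5.03e-09, 0.00963 and 0.0125 for these 3 lists in the order named, and 0.298 for each as an adjusted p with an estimated correlation.

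ERK output genes were low in these resistant cells, with 18 of 20 lower and 2 higher. Etv5 fell by 3.40 (SE 0.08), Dusp4, an ERK phosphatase gene, by 4.35 (SE 0.13), Spry2 by 2.76 (SE 0.08) and Epha2 by 2.45 (SE 0.07). Mitosis genes were higher in 21 of 26 cases, or 22 when adjusted over the list alone, and lower in 1, with Kif20a at 1.68 (SE 0.10) and Birc5 at 1.40 (SE 0.09), and replication genes were higher in 16 and lower in 2 of 26, with Tyms at 1.51 (SE 0.10) and Gins2 at 1.40 (SE 0.09). The stress effectors Trib3, Chac1, Sesn2 and Ddit4, targets of ATF4, fell by 3.72 (SE 0.09), 2.82 (SE 0.10), 2.33 (SE 0.07) and 2.09 (SE 0.07), in a list where 19 of 22 fell and 3 rose. Immediate early genes, listed as a sign of handling, fell in 15 of 21 cases and rose in 4, with Egr3 at -3.85 (SE 0.21) and Nr4a1 at -2.77 (SE 0.15). That list shares Egr1 and Ier3 with the ERK output list, so its fall cannot be read as handling apart from ERK output. Ribosome biogenesis genes fell in 18 of 22 cases, with Odc1 at -0.95 (SE 0.07) and Gnl3 at -0.75 (SE 0.07). The mitochondrially encoded transcripts rose in 13 of 13 cases, with mt-Nd5 at 0.60 (SE 0.06) and mt-Co3 at 0.53 (SE 0.07), and took 2.44 and 2.47% of counts against 1.67 and 1.73% in parental cells. The camera adjusted p was 5.54e-06 for ERK output, 9.22e-05 for mitosis, 0.0125 for both replication and immediate early genes, 2.55e-05 for ATF4, 0.000502 for ribosome biogenesis and 0.00298 for mitochondrial transcripts. With an estimated correlation it was an adjusted p of 0.298 for ERK output, 0.434 for ATF4, 0.631 for mitochondrial transcripts, 0.734 for replication and 0.637 for the others.

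**Figure D2:**
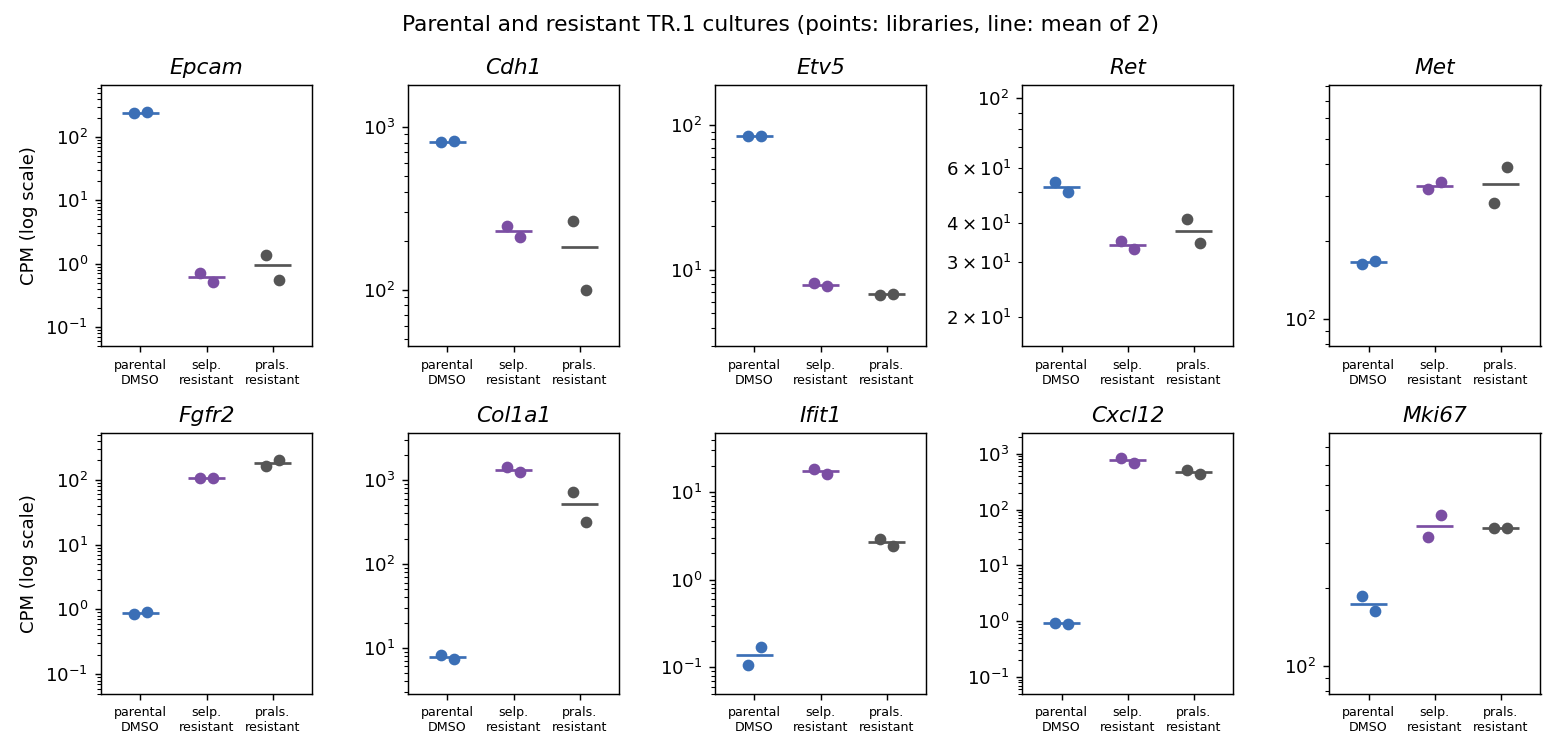
CPM on a log axis for 10 genes in the 6 libraries of the resistance table, with points for libraries and a line for the mean of 2. Epcam lay at 239 and 245 CPM in the parental libraries and at or below 1.38 CPM in the 4 resistant libraries, while Fgfr2 went from 0.860 and 0.929 CPM to between 106 and 203 CPM.

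Many of the genes with the largest change had 0 counts in 1 group, where a fold is a lower bound against 3 counts over the group. Kank4 was at least 1583-fold higher in selpercatinib-resistant cells, Myl9 at least 1259-fold, and Tmem178, Dchs2, Havcr1, Rerg and Dclk3 at least 402-fold. The small leucine-rich proteoglycan gene Dcn rose to 243 ± 37.5 CPM and the Wnt antagonist gene Sfrp2 to 167 ± 12.3 CPM, from 0.0287 and 0.0308 CPM. Aqp8 was at least 2346-fold lower and Cwh43 at least 1182-fold lower. Esrp1, an epithelial splicing regulator, had 2 counts against 13340 in the parental pair, a ratio of 7319.6 with a 95% counting interval from 2026 to 60447. Tns4 and Nptx1 fell from 149 ± 3.95 and 105 ± 2.94 CPM to 0.162 ± 0.0675 and 0.129 ± 0.0337 CPM. edgeR's quasi-likelihood test on all 6 libraries found 10018 of 14389 genes changed, 5062 higher and 4956 lower, of which 2217 and 1591 changed at least 2-fold. Ret fell by 0.61 (SE 0.10), Met rose by 0.98 (SE 0.14), and Trim24 did not pass the test at -0.18 (SE 0.08), edgeR adjusted p = 0.0657, though it passed in a fit to these 4 libraries only at adjusted p = 0.00776.

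In pralsetinib-resistant cells Epcam averaged 0.967 ± 0.584 CPM (SD, n = 2), 250.3-fold lower than in parental cells, and of 20 epithelial genes 19 fell and none rose. Cldn7, Cldn4 and St14 fell by 7.37 (SE 0.11), 6.78 (SE 0.15) and 7.44 (SE 0.13) on the log2 scale, and Cdh1 fell by 2.16 (SE 0.38). In a fibroblast list where 8 of 10 rose and 1, the collagen gene Col6a3, fell by 1.09 (SE 0.25), Col1a1 was at 516 ± 284 CPM, Col1a2 at 11.58 (SE 0.60), Col3a1 at 9.54 (SE 0.48), Fbn1 at 4.05 (SE 0.21) and Col5a1 at 2.48 (SE 0.11). Here too Col3a1 and Dcn passed the filter only through resistant libraries. The mesenchymal list was not called in these cells, with 9 of 20 genes higher, 9 lower, a median of -0.11 and a camera adjusted p = 0.660. Interferon-stimulated genes rose in 21 of 26 cases and fell in 2, with Ifit2 at 3.61 (SE 0.13), Xaf1 at 2.99 (SE 0.12), Ddx58 at 2.48 (SE 0.11) and Oasl2 at 1.99 (SE 0.13). Antigen presentation genes rose in 14 of 19 cases and fell in 3, with Cd74 at 3.57 (SE 0.22), Psmb10 at 2.22 (SE 0.12) and Tapbp at 1.95 (SE 0.06). Chemokine and cytokine genes rose in 17 of 26 cases and fell in 8, with Cxcl12 at 478 ± 52.8 CPM, Tgfb2 at 6.64 (SE 0.10), Cxcl5 at 3.92 (SE 0.08) and Cxcl1 at 2.39 (SE 0.06). Camera's adjusted p was 1.34e-08 for the epithelial list, 0.00410 for both the fibroblast and the antigen presentation list, 0.000242 for interferon and 0.0133 for chemokines. Each of these had an adjusted p of 0.417 with an estimated correlation.

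The same resistant cells had 18 of 20 ERK output genes lower and 2 higher, with Etv5 at -3.62 (SE 0.08), Fosl1 at -3.04 (SE 0.09), Spry2 at -2.80 (SE 0.08) and Epha2 at -2.44 (SE 0.07). Mitosis genes rose in 21 of 26 cases, or 22 when adjusted over the list alone, and fell in 1, and replication genes rose in 18 and fell in 2 of 26, with Kif20a at 1.63 (SE 0.10), Birc5 at 1.47 (SE 0.09), Tyms at 1.49 (SE 0.10) and Gins2 at 1.28 (SE 0.09). Glycolysis and hypoxia genes fell in 18 of 23 cases and rose in 2, with Slc2a1 at -1.63 (SE 0.10), the hexokinase gene Hk2 at -1.26 (SE 0.06) and the angiogenic factor gene Vegfa at -1.89 (SE 0.09), while the carbonic anhydrase gene Car12 rose by 2.43 (SE 0.10). ATF4 list genes fell in 19 of 22 cases and rose in 3, with Trib3 at -4.00 (SE 0.09) and Chac1 at -2.72 (SE 0.10). Immediate early genes fell in 15 of 21 cases and rose in 3, with Egr3 at -5.30 (SE 0.23) and Nr4a1 at -3.50 (SE 0.16), and ribosome biogenesis genes fell in 16 of 22 and rose in 2. The mitochondrially encoded transcripts rose in 13 of 13 cases, with mt-Nd5 at 0.94 (SE 0.06) and mt-Cytb at 0.84 (SE 0.06), and took 3.13 and 3.16% of counts. The camera adjusted p was 3.27e-06 for ERK output, 0.00860 for replication, 0.00889 for glycolysis, 3.41e-05 for ATF4, 0.00257 for immediate early genes, 0.0120 for ribosome biogenesis, and 0.000242 for both mitosis and mitochondrial transcripts. With an estimated correlation it was an adjusted p of 0.318 for ERK output, 0.417 for ATF4, 0.705 for immediate early genes, 0.621 for mitochondrial transcripts and 0.711 for the others.

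Among the largest rises Nxph1, Myl9, Dclk3, Tmem178, Dchs2 and Kank4 had 0 counts in parental cells and were at least 445-fold higher in pralsetinib-resistant cells. Sfrp2 rose to 207 ± 31.4 CPM, Postn, which encodes the matrix protein periostin, to 288 ± 196 CPM, and Dcn to 147 ± 71.6 CPM. Kcnk1 was at least 748-fold lower, and Ppp2r2c, Tns4, Slc14a1, Dynap and Tmprss11e were between 763-fold and 2276-fold lower. edgeR's quasi-likelihood test found 10118 of 14389 genes changed, 5145 higher and 4973 lower, of which 2257 and 1720 changed at least 2-fold. Ret fell by 0.46 (SE 0.10) and Trim24 by 0.29 (SE 0.08), and Met rose by 1.01 (SE 0.14).

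**Figure D3:**
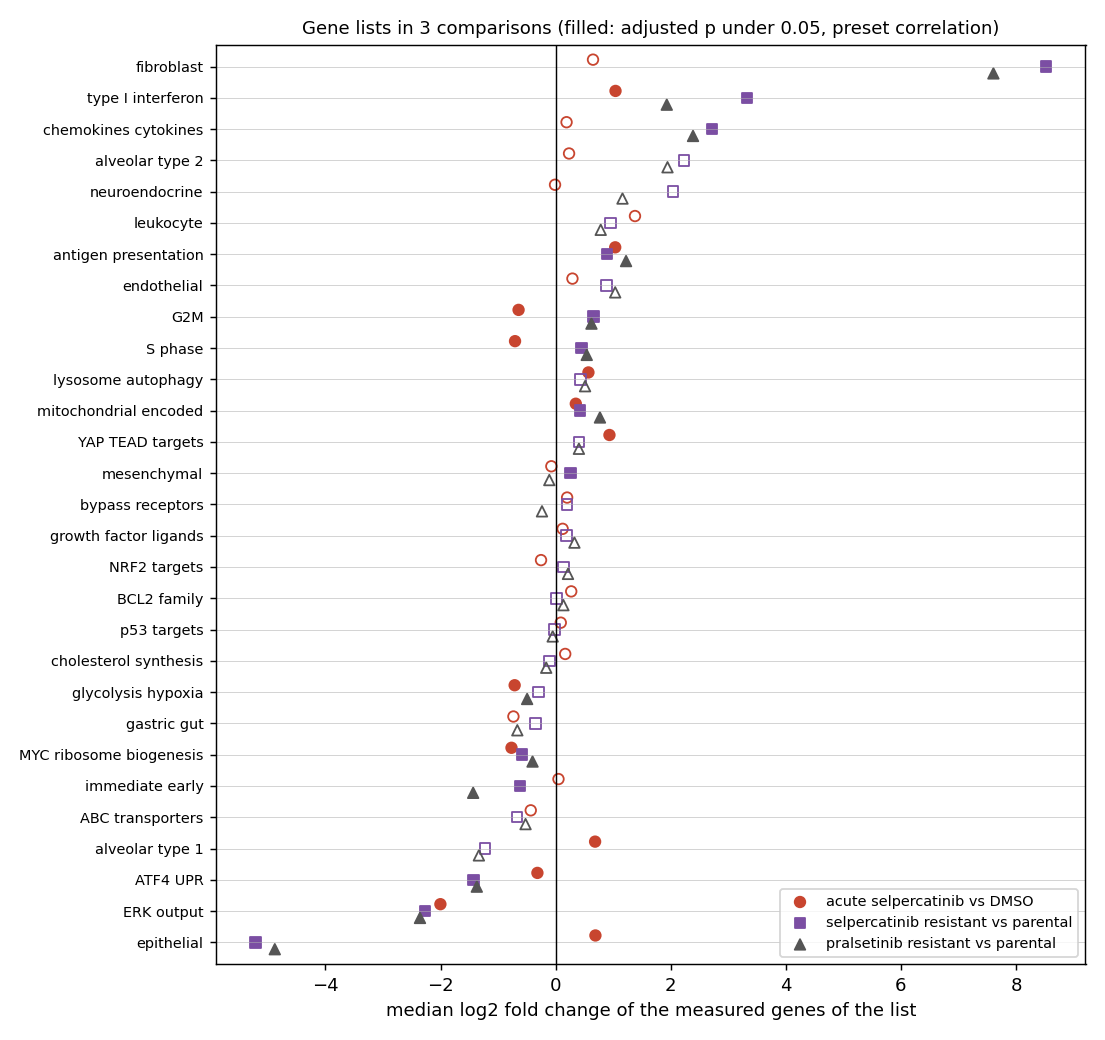
Median log2 fold change of the measured genes of 29 lists (x axis) in 3 comparisons, with circles for acute selpercatinib, squares for selpercatinib-resistant and triangles for pralsetinib-resistant cells, filled where the camera test passed with its preset correlation. The epithelial list had a median of 0.69 after acute selpercatinib and of -5.21 and -4.88 in the resistant groups, while ERK output lay at -2.00, -2.27 and -2.36.

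The resistant groups shared most of their differences from parental cells. Calls in both comparisons numbered 4517 higher and 4371 lower genes, where independent lists would share 1810.0 and 1713, and 33 genes were called in opposite directions. The log2 fold changes of 14389 genes had a covariance of 3.73 and a correlation of 0.974 across genes, which are not independent replicates. Simulated unchanged groups set against the same 2 parental libraries gave a covariance of 0.0156, a correlation of 0.502 and at most 1 shared call in each direction. As no gene was changed in that simulation, few calls could arise. It therefore does not show how many shared calls the controls add where many genes are changed. The simulated covariance was at most 0.0166, which argues against the shared controls as the main source of the covariance of 3.73. Part of the excess of shared calls over independent lists may still come from the shared controls, and with 2 parental libraries no split leaves 2 for each comparison.

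Genes that changed within 5 days of selpercatinib mostly had the same direction in the resistant groups, whose libraries are not those of the acute table. The resistant cultures grew in inhibitor and the parental cells in DMSO, so resistance and the presence of inhibitor cannot be told apart here. Of the 200 genes with the lowest p among those that rose acutely, 193 were measured in the resistance table, and 146 were higher and 25 lower in selpercatinib-resistant cells. In pralsetinib-resistant cells 150 were higher and 25 lower, with a median of 1.29. Of the 200 that fell acutely, 196 were measured, and 170 and 172 were lower, with medians of -1.63 and -1.87. These calls held with an estimated correlation, at a camera adjusted p = 0.0449 for the set that rose and 0.00123 for the set that fell, in both groups. Among 12988 genes tested in both tables, 1915 of 3397 that rose acutely were higher in selpercatinib-resistant cells, where independent lists would share 1086, and 2161 of 3528 that fell were lower, where independent lists would share 1298. Fisher's exact test gave odds ratios of 4.25 and 4.13, and of 3.99 and 4.03 for pralsetinib-resistant cells, on genes that are not independent.

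The direct comparison of the resistant groups asks where cells resistant to selpercatinib differ from cells resistant to pralsetinib, at labelled doses that differ, 500 nM against 200 and 400 nM. Interferon-stimulated genes were higher in selpercatinib-resistant cells in 19 of 26 cases, or 21 when adjusted over the list alone, and lower in none. Ifit1 averaged 17.4 ± 1.57 CPM in selpercatinib-resistant and 2.70 ± 0.368 CPM in pralsetinib-resistant cells (SD, n = 2 each), 6.44-fold higher, with Ifi44, Isg15 and Oasl2 at 3.65 (SE 0.22), 2.37 (SE 0.15) and 1.49 (SE 0.12) on the log2 scale. Glycolysis and hypoxia genes were higher in 12 of 23 cases, or 16 with 1 lower over the list alone, with Pdk1 at 0.99 (SE 0.10), Bnip3 at 0.98 (SE 0.11), Pfkp at 0.82 (SE 0.09) and P4ha1 at 0.52 (SE 0.08). Mesenchymal genes were higher in 9 of 20 cases and lower in 1, or 12 and 2 over the list alone, including Tgfbi at 2.38 (SE 0.15), Lox at 1.54 (SE 0.21), the transcription factor gene Snai2 at 0.94 (SE 0.11) and Spp1 at 0.58 (SE 0.08). In the fibroblast list 5 of 10 were higher and 1 lower, or 8 and 2 over the list alone, with Col6a3 at 2.01 (SE 0.24). Immediate early genes were higher in 7 of 21 cases and lower in 1, or 9 and 2 over the list alone, with Socs3 at 1.59 (SE 0.24), and ERK output genes in 2 of 20 and lower in 1, or 9 and 1 over the list alone, with Egr1 at 0.89 (SE 0.14) and Dusp4 at -0.57 (SE 0.13). Mitochondrially encoded transcripts were lower in 8 of 13 cases, or 10 over the list alone, with mt-Cytb at -0.42 (SE 0.06), NRF2 target genes were lower in 5 of 20, or 6 over the list alone, and higher in 1, with the glutathione transferase genes Gsta3 at -1.44 (SE 0.19) and Gsta4 at -0.63 (SE 0.07), and 1 ribosome biogenesis gene of 22, or 4 over the list alone, was lower, with Rrp12 at -0.49 (SE 0.12).

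Camera's adjusted p was 1.46e-21 for interferon, 2.55e-06 for glycolysis, 5.85e-05 for mesenchymal, 0.00844 for fibroblast, 0.00393 for immediate early, 0.0355 for ERK output, 1.57e-05 for mitochondrial, 0.0192 for NRF2 and 0.000857 for ribosome biogenesis genes. The adjusted p with an estimated correlation was 0.305, 0.664, 0.427, 0.427, 0.670, 0.427, 0.605, 0.427 and 0.710 in the same order. Outside these lists, the protease gene Prss22 and the hyaluronan synthase gene Has2 were higher in selpercatinib-resistant cells by 2.49 (SE 0.30) and 2.45 (SE 0.19). Nts, the fatty acid receptor gene Cd36, Pou3f1, Icosl and Ccdc141 were lower by between -3.25 (SE 0.59) and -2.12 (SE 0.51). Of these 5, all but Cd36 lost the call in edgeR's fit to these 4 libraries, with adjusted p from 0.0519 to 0.0983, as did Dusp4 (0.0946) and Rrp12 (0.105). These genes, and most of the others followed in this comparison, did not hold the call without selpercatinib-resistant replicate 1. Without replicate 2 these genes and many others did not hold it either. Each of these fits leaves 1 library in that group. Ret at -0.15 (SE 0.10), Trim24 at 0.11 (SE 0.08) and Met at -0.02 (SE 0.13) did not pass the test, which does not show them to be alike. edgeR's quasi-likelihood test found 1523 of 14389 genes different, 929 higher and 594 lower in selpercatinib-resistant cells. The count moved between 8 genes without selpercatinib-resistant replicate 1, 118 without replicate 2 of that group, and 4443 and 3879 without pralsetinib-resistant replicate 1 or 2, and it fell to 568 in a fit to these 4 libraries alone.

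**Figure D4:**
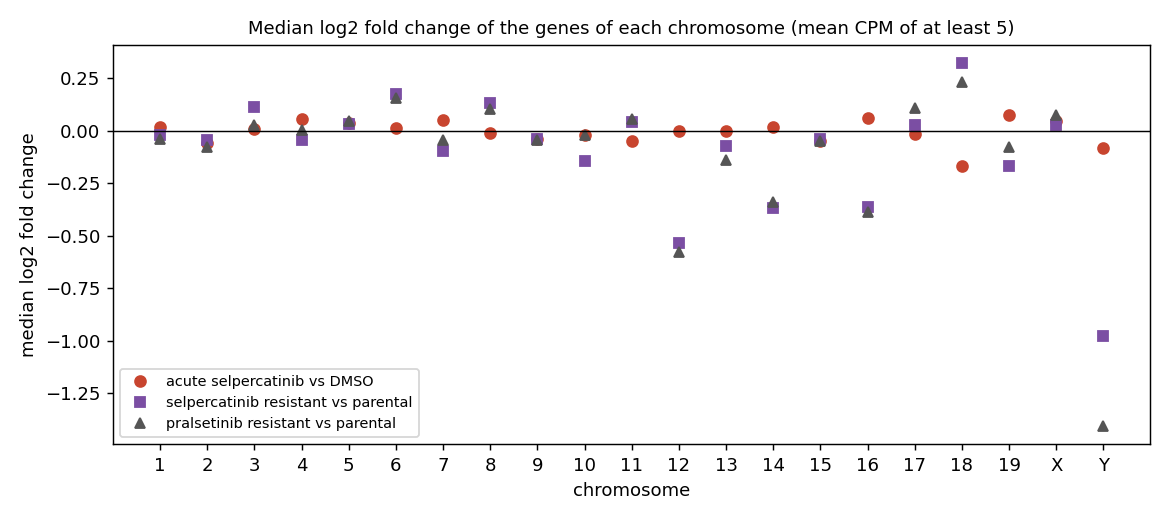
Median log2 fold change (y axis) of the genes of each chromosome (x axis) with a mean of at least 5 CPM, with circles for acute selpercatinib, squares for selpercatinib-resistant and triangles for pralsetinib-resistant cells. The chromosome 12 medians lie at -0.53 and -0.58 in the resistant groups and at 0.00 after acute selpercatinib.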

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

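The tests of other splits of the libraries were chosen before the results were seen, and so was the rule that singles out a library far from the others of its arm. Among 144 groups of acute values tested, 8 had such a library, where chance singles out about 1 in 20, or 7.2. The day 1 library stood apart in selpercatinib, at 0.700 CPM for Aqp8, 2.06 CPM for Nptx1, 1.88 CPM for Slc14a1, 13.3 CPM for Prl2c3 and 11.0 CPM for Prl2c2. In DMSO it was day 1 for Dusp6 at 281 CPM, day 2 for Akap5 at 19.7 CPM and day 5 for Csf1r, a receptor of myeloid growth factor, at 0.620 CPM.

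The effect of selpercatinib differed by day, by the edgeR interaction test, in 164 genes and, by camera at its preset correlation, in 9 lists. Camera with an estimated correlation called 0 lists, and without day 1 or without day 2 edgeR called 0 genes. Per day the edgeR log2 ratio moved by 1.40 for Acta2, 1.06 for Myl9, 0.94 for Cacna1g, 0.93 for Ptprz1 and 0.73 for Tll1. It moved by -1.30 for Mrc1, -1.28 for Serpinb2, -1.04 for Ifi209, -0.99 for Fam78b and -0.92 for Cpa4. The resistant groups differed from each other in 1523 genes and 9 lists. Again camera called 0 lists with an estimated correlation, and without selpercatinib-resistant replicate 1 edgeR called 8 genes. The difference was 2.69 for Ifit1, 2.49 for Prss22, 2.45 for Has2, 2.38 for Tgfbi and 2.37 for Isg15, and -3.25 for Nts, -2.64 for Cd36, -2.43 for Pou3f1, -2.24 for Icosl and -2.12 for Ccdc141. The genes with a negative difference did not hold the call without selpercatinib-resistant replicate 1 or without replicate 2, which leaves 1 library in that group. All but Cd36 also lost it in a fit to the 4 libraries alone. Without replicate 1 most genes followed in this comparison did not hold it, so that loss is not particular to the lower genes.

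With the day term only 8 splits of the acute libraries exist, too few to set the results against chance. The gene count was as large in 1 of 8 splits (7072, highest other 0), the list count in 1 of 8 (13, highest other 10), the count of genes by day in 1 of 8 (164, highest other 0) and the count of lists by day in 5 of 8 (9, highest other 12). Without the day term 1 of 35 splits gave as many genes as the real one, at 5070 against a highest other count of 0. This is the lowest share that 35 splits allow. In the other splits the treatment difference adds to the spread within groups, which keeps their counts low. That fit also leaves out the day that the arms share, so the splits do not exclude chance for its gene count. For lists without the day term 6 of 35 splits gave as many as the real 11, up to 12, so chance is not excluded there.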

How the results depend on the processing

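All counts of changed genes and lists not given here stayed within 1.5 times their value, and the genes followed across settings kept their direction and call in 1215 of 1221 gene and setting pairs of the acute comparison, 1434 of 1439 for selpercatinib-resistant and 1272 of 1285 for pralsetinib-resistant cells. Fewer kept it by day, 220 of 315, and between the resistant groups, 469 of 543. With an estimated correlation camera called 0 lists in every comparison. A higher correlation does not account for each lost call. For ERK output in selpercatinib-resistant cells the estimate was -0.0226, below the preset 0.01, while camera's unadjusted p rose from 5.73e-07 to 0.0121. Fry, which tests each list by itself, called 17 of 29 lists acutely, 7 by day, 25 for selpercatinib-resistant cells, 28 for pralsetinib-resistant cells and 8 between them. In the acute and the 2 parental comparisons 53.5, 69.6 and 70.3% of all genes were called. Fry calls there do not set a list apart from the other genes. Fry's adjusted p for ERK output was 0.00216 acutely and 1.10e-05 in selpercatinib-resistant cells. The 164 genes by day became 971 without a filter, 932 with DESeq2, 418 with the log2 of the day and 5 with early against late days. The 5 negative slopes named were between -0.33 and -0.00328 and not called in limma with a pseudocount of 5. Leaving out a day gave from 0 to 1053 genes and from 3 to 10 lists. The 1523 genes between the resistant groups became 2745 without a filter, 2371 with DESeq2, 568 with only these 4 libraries and from 8 to 4443 without 1 library. The acute set that rose, at -0.14 between the resistant groups, was no longer called with 500 genes (-0.0500) or with an estimated correlation (-0.14). Shared calls fell to 1987 higher and 1439 lower for changes of at least 2-fold, which counts fewer genes. Met, not called, lay between -0.000301 (without replicate 1) and 0.0873 in the acute comparison without 1 day, between -0.0422 and 0.0425 by day and between -0.23 and 0.23 between the resistant groups, where it was called in opposite directions without pralsetinib-resistant replicate 1 (-0.23) and without replicate 2 (0.23), and without selpercatinib-resistant replicate 1 it was 0.0222. Irf7 and Trim24 lost the call in some settings for pralsetinib-resistant cells, and mt-Nd4 lost it acutely without day 2 (0.39). Without the day block the acute counts were 5070 genes and 11 lists. Replicate numbers in the resistance table are only numbers, with a correlation of deviations of -0.108 between parental and selpercatinib-resistant libraries. A replicate block gave 11027 genes and 15 lists for selpercatinib-resistant cells, and a crossed block, chosen after seeing the data, gave 11362 genes. Also chosen after seeing the data, days 1 and 2 alone gave 6965 acute genes, and acute sets without cell cycle genes kept their calls. Except where the construction shows it, the cause was not tested. Depth limits genes near 3 counts, and 2 libraries per group limit the estimate of the spread.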

Other observations

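The tests of replacement by other cells, of fibroblasts, of a response carried on, of clusters and copy number on chromosome 12, of growth state and of scaling were chosen after the results were seen, and the GC and length test before. Receptor tyrosine kinases other than Ret moved both ways, with 11 of 22 higher and 6 lower after acute selpercatinib and 11 of 24 in each direction in both resistant groups, and the list was not called. Fgfr2, a fibroblast growth factor receptor, went from 1.55 ± 0.266 to 21.3 ± 2.43 CPM acutely (SD, n = 4 each). In the resistance table it went from 0.894 ± 0.0487 to 107 ± 1.24 CPM in selpercatinib-resistant and 183 ± 28.1 CPM in pralsetinib-resistant cells (n = 2 each). Fgfr3 rose by 5.31 (SE 0.18) and 6.50 (SE 0.18) on the log2 scale in these groups, while Erbb3, the neuregulin receptor, fell by 3.43 (SE 0.09) and 3.19 (SE 0.09). Acutely Csf1r, Ddr1 and Egfr rose by 3.75 (SE 0.14), 1.51 (SE 0.07) and 1.31 (SE 0.10).

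Ligands of these receptors also moved both ways, with 11 of 23 higher and 6 lower acutely. The EGFR ligands Areg, Btc and Tgfa fell by 3.13 (SE 0.14), 2.99 (SE 0.13) and 1.37 (SE 0.08) acutely, and Tgfa fell by 2.01 (SE 0.07) and 1.84 (SE 0.07) in the resistant groups. Nrg1, a neuregulin, rose by 2.44 (SE 0.08) and 2.51 (SE 0.08), and Hgf, the ligand of Met, rose by 6.59 (SE 0.24) in selpercatinib-resistant cells. Of 14 BCL2 family genes 7 rose and 4 fell acutely, and the list was not called. The apoptosis activators Pmaip1 and Bik rose, Pmaip1 from 22.8 ± 9.11 to 131 ± 22.5 CPM (SD, n = 4 each) and Bik by 2.46 (SE 0.17), and Bcl2 fell by 0.85 (SE 0.08), as did the activator Bcl2l11, named after its value was seen, by 0.55 (SE 0.11). Csf1 and Cxcl10 rose acutely by 2.52 (SE 0.10) and 3.76 (SE 0.18), in a chemokine list that was not called, with 9 of 21 higher and 8 lower. Of the leukocyte and endothelial markers 4 and 5 were measured acutely, with 2 higher in each and 1 and 2 lower. Vim, a mesenchymal filament gene, fell by 0.77 (SE 0.06) and 0.82 (SE 0.06) in the resistant groups.

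In the resistant groups 19 of 20 epithelial genes fell in each and 10 and 8 of 10 measured fibroblast markers rose. Some of these markers, such as Dcn, passed the filter only through resistant libraries. Growth under the inhibitor is a biological hypothesis that could not be tested apart from the groups. Replacement by cells without Ret is argued against by Ret, at -0.61 and still 33.1 and 35.0 CPM in the selpercatinib-resistant libraries. Gene counts do not separate fusion from intact transcripts, so this does not show that cells with the fusion persist. For admixed fibroblasts, the fibroblast transcripts Lum, Thy1 and Dpt reached at most 0.178 CPM in the resistant libraries, where Dcn was at least 96.6 CPM. The markers in this test were picked after their values were seen, in place of Col6a3, at 0.91 (SE 0.23) in selpercatinib-resistant and -1.09 (SE 0.25) in pralsetinib-resistant cells, and Pdgfra, at 0.63 (SE 0.24) and -0.45 (SE 0.25), the last not called. The markers Tcf21 and Fap went from 0.00663 and 0.0946 CPM in parental cells to 0.267 and 0.695 CPM in selpercatinib-resistant cells. In pralsetinib-resistant cells they were at 0.697 and 0.531 CPM. With markers picked in this way the test cannot decide about admixed fibroblasts. A mere continuation of the first 5 days is argued against by the epithelial list, whose acute median was 0.69.

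Genes of chromosome 12 were lower in both resistant groups, at a median of -0.53 and -0.58 over 365 genes. GC content and transcript length do not account for it, since the median nearer to 0 was -0.54 after removing both trends, and a few regulated clusters do not either, since the 20 Mb window nearest to 0 had a median of -0.42. Permuting the chromosome labels gave p = 0.0001, the smallest possible with 10000 permutations, and a lower copy number in the resistant cells could explain it, but DNA was not measured. The medians of chromosome 14 (-0.37 and -0.34), chromosome 16 (-0.36 and -0.39) and 5 genes of chromosome Y (-0.98 and -1.41) were also lower, and those of chromosomes 18 (0.32 and 0.23), 6 (0.17 and 0.15) and 8 (0.13 and 0.10) were higher. Smaller rises of chromosomes 11 (0.04 and 0.05) and 5 (0.03 and 0.05) also passed in both groups. Other shifts passed in 1 group only, among them chromosomes 19 (-0.17), 10 (-0.15) and 3 (0.11) in selpercatinib-resistant and 13 (-0.14) and 17 (0.11) in pralsetinib-resistant cells. Chromosome 18 passed acutely in the other direction (-0.17), and smaller acute shifts of chromosomes 2 (-0.06), 4 (0.05), 7 (0.05) and 19 (0.07) also passed.

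Cell cycle lists rose while ERK output fell in both resistant groups at camera's preset correlation, and with an estimated correlation the adjusted p lay between 0.298 and 0.734. Proliferation without ERK output is a hypothesis that no test here checks. A later growth state of the parental cultures might also raise the difference, as Mki67 in DMSO fell from 689 CPM on day 1 to 69.0 CPM on day 5. The 200 genes that rose most in DMSO by day 5 had a median of -0.23 in pralsetinib-resistant cells, at percentile 0.07 of 10000 random lists, as that state would give, but of -0.13 in selpercatinib-resistant cells, at percentile 13.1, so it remains open. Median of ratios scaling hardly moved the values, with a largest camera adjusted p of 0.0127 for the 3 lists, so it does not decide about scaling.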
